A study of Mus musculus with 43 samples.

How the data were processed

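Poly(A) RNA-seq was deposited for 43 mouse libraries: 34 from reprogramming courses of 4 cell systems and 9 from perturbations of Myc. Secondary mouse embryonic fibroblasts (MEF), which carry doxycycline-inducible reprogramming factors, were induced with doxycycline in medium with fetal bovine serum and LIF at 5% oxygen. Per the design text, serum replacement medium with LIF and inhibitors of MEK and GSK3 replaced it on day 3.5. The growth protocol instead gives an earlier addition of the inhibitors, so the labels differ on this. Per the labels, cells of days 3 to 8, the established induced pluripotent stem cells (iPSC, passage 3 or later) and embryonic stem cells (ES) grew on irradiated human foreskin fibroblasts. Time, medium and feeder layer therefore change together along each course.

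The values are FPKM per gene, deposited by the authors in 5 tables with Ensembl gene identifiers: 1 for each of the 4 systems and 1 for the Myc libraries. The submitters' processing notes name CASAVA 1.8.2, TopHat2 2.0.10, Cufflinks 2.2.1 and the genome build mm10. The annotation release and the use of strand are not given in the sources used here. The library kit named in the labels is the TruSeq RNA kit, whose protocol does not mark strand. Values of overlapping, antisense and near-identical genes are therefore uncertain. Whole reads were not recovered from these estimated FPKM, so the depth of each library is unknown, and no interval for counting error can be given. All 37 mitochondrial genes were listed at 0 in every library, and the number above 0 in any library was 0. A 0 in these tables can therefore be a failed estimate, and no ratio of 2 libraries is given for a gene against a listed 0. The fits take a listed 0 as 0, so changes of genes such as Pou5f1 and Krtdap, listed at 0 in libraries of WT-2, rest in part on such values. In 27 entries the gene symbol had become a date; such genes were identified by their Ensembl identifier. The number of value columns without a matching sample was 0. The tables share 38983 genes. Coordinates were taken from the GRCm38 gene annotation.

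The course libraries were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), so a log2 change understates the change of a gene with a low level. Genes with an FPKM of at least 1 in at least 2 libraries were kept. The spread was moderated with the trend and robust options of eBayes, and p-values were adjusted by Benjamini and Hochberg with a threshold of 0.05. The model gave each class (depleted: Mbd3f/- and Gatad2a-/-; WT: WT-1 and WT-2) a mean at each stage and took the system, which is also the deposited table, as a block. ES aside, each contrast is a difference within a table or of such differences. The comparisons over the stages shared by all 4 systems used 24 libraries, 20305 genes and 10 residual degrees of freedom. The dense course of the 2 depleted systems used 20 libraries, 20198 genes and 9 residual degrees of freedom. The comparison of ES with iPSC used 26 libraries, 20410 genes and 10 residual degrees of freedom. Each stage of a system is 1 library, so n is the number of systems. Nothing in the labels says that the libraries of a system come from separate cultures, so p-values measure the spread between these samples.

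Gene lists were tested with camera in limma at a preset correlation of 0.01, and again with an estimated correlation. The 30 lists cover pluripotency, the induced factors, early epithelial genes, fibroblast identity, smooth muscle and TGF-beta response, ribosome biogenesis with Myc-responsive genes, ribosomal proteins, the cell cycle, senescence and p53 response, glycolysis, oxidative phosphorylation, one-carbon metabolism, NuRD subunits, DNA methylation, Polycomb and other chromatin regulators, germline, 2-cell-like, trophoblast, endoderm, primed epiblast and mesoderm, neural, interferon, inflammatory and imprinted genes, and readouts of LIF, WNT and MEK signalling. They also hold markers of endothelial cells, macrophages and blood, skeletal muscle and keratinocytes, and signs of RNA quality. For each list the members that rose or fell were counted over all genes tested and adjusted over the list alone. In 52 of the 420 list tests, the median, the mean and the camera direction differed in sign, and camera called 0 of these 52.

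Named genes are those with the 10 largest rises and the 10 largest falls among genes past the threshold with an FPKM of at least 5 on the higher side and the same sign in every system. Predicted genes and clone names were left out, and one gene that met the rule is not reported here. Mbd3, Gatad2a, the 4 induced factors and the members of each list with the largest changes were named as well. The groups, tests, lists, naming rule and the alternatives not stated to be added later were set before the data were examined. Progress was computed per library as the median of (library minus MEF) divided by (iPSC minus MEF) in log2(FPKM + 1), within its own table. It used genes called between iPSC and MEF whose difference in that table was at least 2.

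The Myc table has 1 library per condition apart from 2 control MEF replicates, so it was described without a test. Log2 ratios of libraries were formed over 16436 genes, and each list median was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. A list needed at least 3 measured members. Because the largest ratios include short non-coding RNA fragments that also part the 2 control replicates, the genes named from this table are protein-coding, a restriction chosen after seeing the data.

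The procedures were tested on simulated data with 100 genes changed by a log2 of 1 and 100 by a log2 of 2. At 2, among 20305 genes, the test recovered 80% for iPSC against MEF, 61% for depleted day 8 against MEF and 60% for WT day 8 against MEF. Recovery was 58% for depleted day 8 against iPSC and 64% for WT day 8 against iPSC. For the differences between classes it was 23% at day 2, 32% at day 4, 31% at day 6, 15% at day 8 and 22% in iPSC. At 1, the recovery was 42% for iPSC against MEF, 8%, 13%, 9% and 17% for the other 4 comparisons in that order, and 0% for each of the 5 differences between classes. Among 20198 genes, the recovery at 2 was 59% for day 1 against MEF, 74% for day 4 against day 1 and 73% for day 8 against day 4, and at 1 it was 13%, 20% and 15%. For ES against iPSC it was 70% at 2 and 30% at 1, among 20410 genes. Of the genes called in the simulation, 2.67% to 9.46% were unchanged genes, above 5% in 9 of the 14 comparisons and highest for depleted day 8 against iPSC. For the random lists, 5% of 200 simulated lists of 20 genes lay above percentile 95 with no shift, and 100% with a shift of 0.5. A simulated trend in GC content and length moved a correlation of -0.635 to -0.006 over 13240 genes once it was removed.

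Alternatives were a pseudocount of 0.1, no filter, quantile normalization, upper quartile scaling, no system block, eBayes without trend and robust, only the libraries of the compared stages, and leaving out each system in turn. Alternatives chosen after seeing the data were protein-coding genes only, and leaving out the iPSC libraries of Mbd3f/- and WT-1. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for the progress and Myc values, and matplotlib 3.10.9 for the plots.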

Results

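Gene expression was measured in mouse fibroblasts on their way to induced pluripotency, in cells with and without a reduced dose or loss of subunits of NuRD, a chromatin remodelling and deacetylase complex. The Mbd3f/- system contributed 11 libraries: MEF, each of days 1 to 8 of induction, an established iPSC line and an ES line. The Gatad2a-/- system contributed 10 libraries, the same without ES. The wild-type system WT-1 contributed 7 libraries (MEF, days 2, 4, 6 and 8, iPSC and ES), and WT-2, isogenic to Gatad2a-/-, contributed 6 (without ES). A further table held 9 libraries with altered Myc. Levels in different tables, normalized separately, are set side by side below and, ES aside, tested only within a table. The number of genes at an FPKM of at least 1 ranged from 12266 to 13861 in Mbd3f/-, from 12321 to 13161 in WT-1, from 13197 to 13983 in WT-2 and from 15485 to 16896 in Gatad2a-/-. The depth of the libraries is unknown.

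Mbd3, the methyl-CpG-binding-domain subunit of NuRD, and Gatad2a, a zinc finger subunit of the same complex, were examined in every library before any comparison. Mbd3 (ENSMUSG00000035478) lies on the minus strand of chromosome 10 at 80392539 to 80399550 (GRCm38) and has 7 exons. Its FPKM was 37.5 in Mbd3f/- MEF, 96.5 on day 1, 81.1 on day 2, 79.8 on day 3, 57.5 on day 4, 60.8 on day 5, 58.0 on day 6, 55.8 on day 7, 61.6 on day 8, 43.1 in iPSC and 36.3 in ES. In WT-1 it was 79.4 in MEF, 75.3, 117, 104 and 102 on days 2, 4, 6 and 8, 101 in iPSC and 99.3 in ES. In Gatad2a-/- it was 64.5 in MEF, 84.6, 65.6, 63.2, 77.6, 72.2, 62.7, 68.2 and 67.4 on days 1 to 8, and 81.3 in iPSC. In WT-2 it was 53 in MEF, 68.2, 74.0, 75.7 and 76.6 on days 2, 4, 6 and 8, and 135 in iPSC. Gatad2a (ENSMUSG00000036180) lies on the minus strand of chromosome 8 at 69907076 to 69996384 and has 12 exons. In Gatad2a-/- its FPKM was 10.2 in MEF, 12.4, 9.18, 8.59, 10.3, 9.30, 10.5, 13.1 and 14.7 on days 1 to 8, and 13.4 in iPSC. In WT-2 it was 10.5 in MEF, 11.5, 11.1, 9.5 and 9.17 on days 2, 4, 6 and 8, and 38.5 in iPSC. In WT-1 it was 13.0 in MEF, 10.7, 13.8, 13.2 and 11.8 on days 2, 4, 6 and 8, 29.9 in iPSC and 42.2 in ES. In Mbd3f/- it was 10.3 in MEF, 30.1, 30.7, 31.1, 20.4, 24.9, 23.0, 29.1 and 33.7 on days 1 to 8, 37.8 in iPSC and 21.3 in ES. Neither targeted gene was listed at 0 in the system that lacks it in part or whole. RNA of a disrupted allele can still be counted, and the disrupted part of each gene is not given in the sources used here. In the fits, Mbd3 changed by 0.55 ± 0.21 (SE) between MEF and iPSC over the 4 systems (limma adjusted p = 0.040), and Gatad2a by 1.27 ± 0.23 (adjusted p = 0.00036).

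Established iPSC were compared with MEF in all 4 systems to set the end points of the courses. Dppa5a (ENSMUSG00000060461), an RNA-binding protein gene of the early embryo, rose by 10.01 ± 0.64 on the log2 scale (SE, n = 4 systems; limma adjusted p = 8.8e-08). Pou5f1 (ENSMUSG00000024406, chromosome 17 at 35506018 to 35510772, plus strand), a core pluripotency transcription factor and an induced factor, rose by 9.80 ± 0.88 (adjusted p = 1.4e-06). Next were Tdgf1 (8.71 ± 0.66), a co-receptor for Nodal, Nanog (7.77 ± 0.53), a pluripotency homeobox factor, the threonine dehydrogenase gene Tdh (7.72 ± 0.83) and the uridine phosphorylase gene Upp1 (7.44 ± 0.62). Further rises were those of Trap1a (7.38 ± 0.33), the thyrotropin-releasing hormone gene Trh (7.33 ± 1.00), the orphan nuclear receptor gene Esrrb (7.18 ± 0.33) and L1td1 (7.18 ± 1.08). Bgn (ENSMUSG00000031375), the proteoglycan biglycan, changed by -8.73 ± 0.41 (adjusted p = 7.6e-09), and the collagen-crosslinking oxidase Lox by -8.04 ± 0.37. The other largest falls were those of smooth muscle actin Acta2 (-7.95 ± 0.68), matrix Gla protein Mgp (-7.65 ± 0.53), the chemokine gene Cxcl12 (-7.50 ± 0.64). Also among them were the collagen genes Col1a2 (-7.25 ± 0.75), Col5a2 (-7.19 ± 0.38) and Col6a1 (-7.15 ± 0.36), the lysozyme gene Lyz2 (-7.20 ± 1.10) and thrombospondin Thbs1 (-7.20 ± 0.47). Of the other induced factors, Sox2 rose by 6.78 ± 0.63 and Klf4 by 2.33 ± 0.66, and Myc had a change of -0.97 ± 1.01 (adjusted p = 0.446). FPKM of these factors can include transgene reads. In all, 5895 genes rose and 4859 fell; 9660 of these 10754 had the same sign in all 4 systems. Without the system block 6411 genes passed, and Lyz2 lost its call.

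All 30 pluripotency genes rose, also when adjusted over the list alone (camera adjusted p = 7.84e-17, and adjusted p = 0.124 with an estimated correlation). Of 4 induced factors 3 rose, adjusted over the list alone as well, without a camera call (adjusted p = 0.0752). In the epithelial list 14 of 20 genes rose, 1 fell and 5 did neither (16 and 1 adjusted over the list alone; camera adjusted p = 0.000458, and adjusted p = 0.373 with an estimated correlation), including the adhesion genes Epcam (4.80 ± 0.83) and Cdh1 (4.77 ± 0.83). In the fibroblast list 31 of 32 fell (32 adjusted over the list alone; camera adjusted p = 2.98e-20, and adjusted p = 0.124 with an estimated correlation). All 14 smooth muscle and TGF-beta genes fell, among them Tagln (-6.83 ± 0.58) and Actg2 (-6.68 ± 0.35), both contractile (14 adjusted over the list alone; camera adjusted p = 2.34e-10, and adjusted p = 0.124 with an estimated correlation). Ribosome biogenesis and Myc-responsive genes rose in 44 of 45 cases, led by the transferrin receptor Tfrc (3.76 ± 0.52), Nhp2 (3.03 ± 0.38) and Dkc1 (2.89 ± 0.44), and 44 adjusted over the list alone (camera adjusted p = 1.79e-11, and adjusted p = 0.373 with an estimated correlation). All 38 cell cycle genes rose, led by Mybl2 (5.88 ± 0.43) and the helicase subunit Mcm5 (3.76 ± 0.45), and 38 adjusted over the list alone (camera adjusted p = 1.47e-12, and adjusted p = 0.373 with an estimated correlation). Ribosomal protein genes rose in 34 of 39 cases (35 adjusted over the list alone), with Rpl8 at 1.19 ± 0.23 (camera adjusted p = 5.51e-06, and adjusted p = 0.505 with an estimated correlation). Oxidative phosphorylation genes rose in 30 of 32 cases (31 adjusted over the list alone), with Cyc1 at 1.87 ± 0.24 (camera adjusted p = 7.56e-08, and adjusted p = 0.373 with an estimated correlation). One-carbon genes rose in 14 of 16 cases (15 adjusted over the list alone), with Shmt1 at 4.25 ± 0.50 (camera adjusted p = 5.51e-06, and adjusted p = 0.373 with an estimated correlation). Glycolysis had 6 genes up, 4 down and 14 neither (5 and 4 adjusted over the list alone), with the glucose transporter Slc2a3 at 4.97 ± 0.60 and Eno2 at -2.65 ± 0.41 (camera adjusted p = 0.707).

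Among chromatin lists, NuRD subunits had 8 genes up, 2 down and 4 neither (8 and 3 adjusted over the list alone; camera adjusted p = 0.275), with Chd3 at -2.87 ± 0.31, Hdac1 at 1.82 ± 0.20 and Mbd2 at -1.70 ± 0.18. DNA methylation genes had 8 up, 2 down and 2 neither, and 8 and 2 adjusted over the list alone, led by the methyltransferase cofactor Dnmt3l (5.60 ± 0.57) and the methyltransferase Dnmt3b (3.92 ± 0.34; list camera adjusted p = 0.0129, and adjusted p = 0.219 with an estimated correlation). Polycomb and other chromatin regulators had 16 up, 2 down and 4 neither, and 16 and 2 adjusted over the list alone (Utf1 6.49 ± 0.49, Cbx7 4.92 ± 0.29; camera adjusted p = 0.000313, and adjusted p = 0.373 with an estimated correlation). Germline genes had 16 up, 1 down and 3 neither, and 18 and 1 adjusted over the list alone (Tex19.1 4.52 ± 0.56, Sohlh2 4.11 ± 0.28; camera adjusted p = 2.14e-05, and adjusted p = 0.373 with an estimated correlation). Imprinted genes had 2 up, 13 down and 3 neither, with 2 and 13 adjusted over the list alone, including Dlk1 (-7.14 ± 0.41), H19 (-6.36 ± 0.71), Igf2 (-6.24 ± 1.15) and Meg3 (-4.32 ± 0.62; list camera adjusted p = 0.000214, and adjusted p = 0.124 with an estimated correlation). Endoderm genes had 1 up and 8 down of 9, likewise adjusted over the list alone (Dab2 -5.17 ± 0.51; camera adjusted p = 0.000458, and adjusted p = 0.219 with an estimated correlation). Primed epiblast and mesoderm genes rose in 5 of 9 cases and in 6 adjusted over the list alone (Nodal 5.09 ± 0.55; camera adjusted p = 0.00472, and adjusted p = 0.219 with an estimated correlation). Interferon genes fell in 15 of 20 cases, and in 15 adjusted over the list alone (Isg15 -4.67 ± 0.91; camera adjusted p = 0.00018, and adjusted p = 0.505 with an estimated correlation). Inflammatory genes fell in 12 of 18 cases, and in 12 adjusted over the list alone (Csf1 -5.21 ± 0.28; camera adjusted p = 4.82e-05, and adjusted p = 0.373 with an estimated correlation). Macrophage and blood markers fell in 6 of 8 cases, and in 6 adjusted over the list alone (Tyrobp -5.59 ± 1.08; camera adjusted p = 0.0129, and adjusted p = 0.505 with an estimated correlation). No camera call was made for senescence and p53 response (4 up, 6 down, 10 neither; adjusted p = 0.275), 2-cell-like genes (1 up, 1 down, 8 neither; 0.371), trophoblast genes (6 up, 1 down, 6 neither; 0.0963) or neural genes (4 up, 3 down, 3 neither; 0.896), with the same counts adjusted over each list alone. The same held for readouts of LIF, WNT and MEK (9 up, 8 down, 2 neither; 9 and 9 adjusted over the list alone; camera adjusted p = 0.453). It also held, with equal counts adjusted over each list alone, for endothelial (2 up, 1 down, 3 neither; 0.362), skeletal muscle (1 up, 3 down, 2 neither; 0.453) and keratinocyte markers (2 up, 1 down, 6 neither; 0.997) and for signs of RNA quality (2 up, 2 down, 5 neither; 0.896). Over the 14 contrasts, camera called 205 of 420 list tests at the preset correlation and 0 with an estimated correlation, where the lowest adjusted p was 0.0562.

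Progress from MEF to iPSC, measured within each table, was further on in both depleted systems than in both WT systems on each shared day. In Mbd3f/- the median over 2645 genes was 0.417 on day 1, 0.628 on day 2, 0.755 on day 3, 0.763 on day 4, 0.919 on day 5 and 0.974 on day 8. In Gatad2a-/- the median over 2429 genes was 0.290 on day 1, 0.343 on day 2, 0.515 on day 3, 0.695 on day 4, 0.822 on day 5 and 0.910 on day 8. WT-1 reached 0.233 on day 4 and 0.320 on day 8 (2639 genes), and WT-2 reached 0.0877 on day 4 and 0.0459 on day 8 (3485 genes). At day 8 the depleted systems had a mean of 0.942 ± 0.0455 (SD, n = 2) and the WT systems 0.183 ± 0.194 (SD, n = 2). In the depleted systems genes lower in iPSC than in MEF were ahead of genes higher in iPSC on day 4. Their median was 0.945 (1499 genes) against 0.334 (1146 genes) in Mbd3f/-, and 0.844 (1375 genes) against 0.435 (1054 genes) in Gatad2a-/-. In the WT systems the order varied: on day 8 it was 0.278 against 0.383 in WT-1, or 0.313 against 0.284 after quantile normalization, and 0.130 against 0 in WT-2. The difference between the classes in progress has no test of its own. It was 0.759 at day 8, and ranged from 0.762 to 0.776 under the alternatives.

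**Figure D1:**
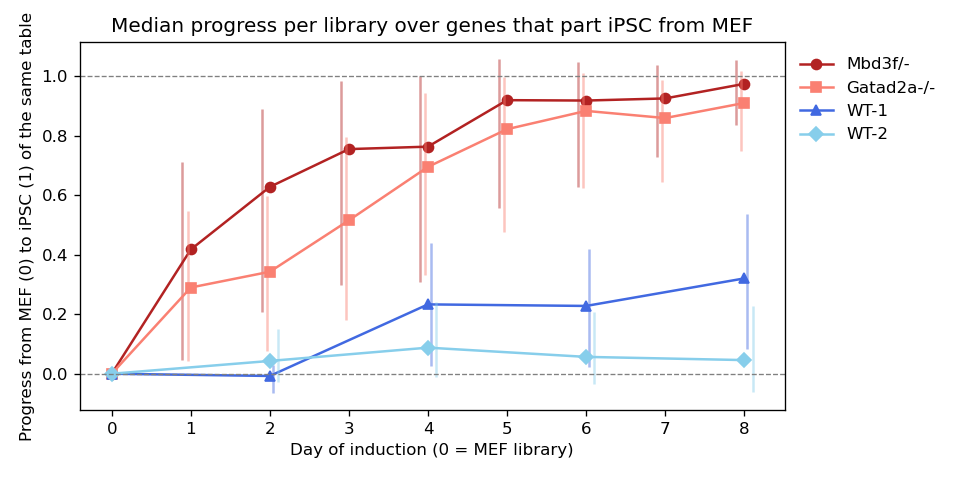
Median progress of each library (vertical axis, 0 at the MEF and 1 at the iPSC library of the same table) by day of induction, with bars from the lower to the upper quartile over genes; 1 library per point. At day 8 Mbd3f/- stood at 0.974, Gatad2a-/- at 0.910, WT-1 at 0.320 and WT-2 at 0.0459.

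Day 8 cells of the depleted systems were compared with their own MEF to see how much of the fibroblast program had been replaced. Dppa5a rose by 10.04 ± 0.91 (SE, n = 2 systems; limma adjusted p = 6.3e-06), Pou5f1 by 9.37 ± 1.25 and Tdgf1 by 8.46 ± 0.94. They were followed by Tdh (7.26 ± 1.18), Nanog (7.07 ± 0.75), Fam25c (6.97 ± 0.82), Trap1a (6.96 ± 0.47), Esrrb (6.95 ± 0.47) and Fbxo15 (6.76 ± 0.65). Tdgf1-ps1 (6.83 ± 0.92), a pseudogene, resembles Tdgf1 and its reads cannot be told from those of the parent with certainty. The largest falls were in contractile genes, Acta2 (-9.28 ± 0.96), Tagln (-8.02 ± 0.83) and Actg2 (-7.83 ± 0.49), and in matrix genes, Bgn (-8.03 ± 0.58), Lox (-7.83 ± 0.52), Postn (-7.43 ± 0.74) and Mgp (-7.39 ± 0.74). Lyz2 (-7.63 ± 1.55), the growth factor gene Ptn (-7.44 ± 0.73) and the imprinted gene Dlk1 (-7.39 ± 0.58) fell as well. In the pluripotency list 29 of 30 genes rose (30 adjusted over the list alone; camera adjusted p = 1.31e-17, and adjusted p = 0.109 with an estimated correlation). All 32 fibroblast genes fell, 32 adjusted over the list alone (camera adjusted p = 9.57e-25, and adjusted p = 0.102 with an estimated correlation). In the epithelial list 15 of 20 rose and 1 fell, with Epcam at 5.10 ± 1.18 and Cdh1 at 4.94 ± 1.17 (16 and 1 adjusted over the list alone; camera adjusted p = 3.71e-05, and adjusted p = 0.36 with an estimated correlation). Ribosome biogenesis genes rose in 33 of 45 cases (37 adjusted over the list alone; camera adjusted p = 7.92e-07, and adjusted p = 0.477 with an estimated correlation). Cell cycle genes rose in 26 of 38 (30 adjusted over the list alone; camera adjusted p = 2.83e-07, and adjusted p = 0.461 with an estimated correlation). LIF, WNT and MEK readouts fell in 9 of 19 cases and rose in 1, with the immediate early gene Egr1 at -5.62 ± 0.82 (10 and 1 adjusted over the list alone; camera adjusted p = 0.00446, and adjusted p = 0.371 with an estimated correlation). Macrophage and blood markers fell in 6 of 8 cases, and in 6 adjusted over the list alone (camera adjusted p = 0.00598, and adjusted p = 0.461 with an estimated correlation). In all, 3868 genes rose and 3101 fell, 6969 together. The median change of all genes was 0.234, and 0.104 after quantile normalization. Without Gatad2a-/- 4023 genes passed, without the system block 2910 (1327 up and 1583 down) and with only the compared stages 4588. Pou5f1, Tdh, Tdgf1-ps1 and Lyz2 lost their call without Mbd3f/-, and Lyz2 also without Gatad2a-/- and without the system block.

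In the WT systems the same comparison called fewer genes, and no pluripotency gene. Mmp3, a matrix metalloproteinase gene, rose by 5.40 ± 1.13 (SE, n = 2 systems; limma adjusted p = 0.042). Clec3b rose by 5.37 ± 1.05, the prostaglandin D synthase gene Ptgds by 4.38 ± 0.73 and the retinoic acid binding protein gene Crabp1 by 4.29 ± 0.70. Steap4 (4.09 ± 0.58), dermatopontin Dpt (4.05 ± 0.69), Cd55 (4.01 ± 0.55), Cpz (4.00 ± 0.66), the chemokine gene Cxcl1 (3.77 ± 0.70) and Angptl4 (3.70 ± 0.67) also rose. Among the genes that fell were Cdsn (-4.42 ± 0.78, adjusted p = 0.022) and the lactate transporter gene Slc16a3 (-4.00 ± 0.68). Others were Lect1 (-3.46 ± 0.67), Dlk1 (-3.42 ± 0.58), Rbpsuh-rs3 (-3.38 ± 0.53) and the cartilage collagen gene Col2a1 (-3.38 ± 0.67). Of smooth muscle and TGF-beta genes 3 of 14 fell, with Thbs1 at -3.06 ± 0.67 and Ctgf at -2.84 ± 0.56 (5 adjusted over the list alone; camera adjusted p = 1.9e-06, and adjusted p = 0.69 with an estimated correlation). Of 24 glycolysis genes 2 fell (9 down and 1 up adjusted over the list alone; camera adjusted p = 1.9e-06, and adjusted p = 0.82 with an estimated correlation). Of 32 oxidative phosphorylation genes 2 rose, Ndufa4 (1.17 ± 0.24) and Cox6c (1.04 ± 0.21; 6 adjusted over the list alone; camera adjusted p = 6.58e-12, and adjusted p = 0.69 with an estimated correlation). Camera placed the 30 pluripotency genes higher as a list (adjusted p = 6.79e-06, and adjusted p = 0.82 with an estimated correlation), while limma called 0 members over all genes and 0 adjusted over the list alone. Pou5f1 had a change of 3.41 ± 1.25 (adjusted p = 0.207). The fibroblast list had 0 members past the threshold, 3 up and 4 down adjusted over the list alone (camera adjusted p = 0.905). In all, 89 genes rose and 146 fell (235; 3076 at an unadjusted p under 0.05), and 217 and 105 without WT-2. Without Mbd3f/- 40 genes passed and without Gatad2a-/- 1, with 0 of the 20 genes picked by the naming rule in both cases. Without the system block 1 passed, without the filter 112, and with only the compared stages 0 (1930 at an unadjusted p under 0.05).

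Whether depleted and WT systems changed differently was tested as an interaction at each shared day, the depleted change from MEF minus the WT change. At day 2, Nov, a matricellular protein gene, was lower in the depleted change (-6.08 ± 0.52, SE, n = 2 systems per class, limma adjusted p = 0.00021). It was followed by Col12a1 (-5.82 ± 0.86), Cxcl12 (-5.74 ± 1.28), Ogn (-5.61 ± 0.79), Postn (-5.41 ± 1.05), Serpina3g (-5.41 ± 1.00), Mfap2 (-5.38 ± 0.81) and Ptn (-5.28 ± 1.03). Higher in the depleted change were Fetub (5.93 ± 1.24), the aquaporin gene Aqp3 (5.21 ± 0.80), the epidermal fatty acid hydroxylase gene Cyp4f39 (4.98 ± 0.75), and the non-coding RNA Miat (4.12 ± 0.56). Plek2 (4.09 ± 0.54), Rapgef4 (4.05 ± 0.67), Cited1 (3.93 ± 0.61) and the keratinocyte differentiation gene Krtdap (3.78 ± 0.83) were higher as well. Of 32 fibroblast genes 12 were lower, including Col1a1 (-4.74 ± 0.98) and Lox (-4.68 ± 0.73; 22 adjusted over the list alone; camera adjusted p = 2.61e-21, and adjusted p = 0.127 with an estimated correlation). Of 45 ribosome biogenesis genes 3 were higher over all genes and 41 adjusted over the list alone, with nucleolin Ncl at 2.66 ± 0.64 (camera adjusted p = 1.4e-20, and adjusted p = 0.38 with an estimated correlation). Of 30 pluripotency genes 0 passed over all genes and 1 was lower adjusted over the list alone (camera adjusted p = 0.224). In all, 113 genes were higher and 380 lower (493), a split that turned to 1464 and 801 without Mbd3f/-. Without Mbd3f/-, Gatad2a-/-, WT-1 or WT-2 the count was 2265, 851, 57 and 49, and 7, 13, 5 and 7 of the 20 named genes kept their call. It was 255 with a pseudocount of 0.1, 306 without the filter, 28 without the system block, 0 with only the compared stages (3689 at an unadjusted p under 0.05) and 799 among protein-coding genes only.

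By day 4 the keratinocyte differentiation gene Krtdap (6.88 ± 0.83, SE, n = 2 systems per class; limma adjusted p = 0.00067), Cyp4f39 (6.60 ± 0.75) and Aqp3 (6.33 ± 0.80) led the genes that were higher in the depleted change. They were followed by Fetub (5.53 ± 1.24), Fam25c (5.17 ± 1.16), the galectin gene Lgals7 (5.12 ± 0.85), Stmn2 (4.88 ± 0.97), Ly6g6c (4.67 ± 1.18), Nanog (4.38 ± 1.06, adjusted p = 0.028) and Cnpy1 (4.07 ± 0.63). Lower were the insulin-like growth factor binding protein genes Igfbp5 (-8.87 ± 1.65) and Igfbp3 (-7.12 ± 1.92), Mgp (-8.24 ± 1.05), and the imprinted RNA H19 (-8.21 ± 1.43). Also lower were Ptn (-7.70 ± 1.03), Mfap4 (-7.10 ± 1.45), Bgn (-7.07 ± 0.82), elastin Eln (-6.94 ± 1.56), Serpinf1 (-6.88 ± 0.83) and Thbs2 (-6.75 ± 0.61). In the pluripotency list 4 of 30 genes were higher, including Utf1 (3.84 ± 0.98) and Nr0b1 (3.76 ± 0.81; 8 adjusted over the list alone; camera adjusted p = 1.9e-05, and adjusted p = 0.44 with an estimated correlation). In the fibroblast list 24 of 32 were lower (31 adjusted over the list alone; camera adjusted p = 5.36e-27, and adjusted p = 0.0771 with an estimated correlation). Of 9 keratinocyte markers, 1 was higher, Lgals7, and 1 lower, without a camera call (2 and 1 adjusted over the list alone; adjusted p = 0.273). Of imprinted genes 5 of 18 were lower (9 adjusted over the list alone; camera adjusted p = 0.000313, and adjusted p = 0.186 with an estimated correlation). In all, 227 genes were higher and 1083 lower (1310), 17.3% higher, and 31.6% higher after quantile normalization. Without Mbd3f/- the split turned to 1963 and 1373. Without Mbd3f/-, WT-1 or WT-2 the count was 3336, 710 and 241, and 12, 14 and 13 of the 20 named genes kept their call (12 without Gatad2a-/-). Without the system block it was 205, and 283 with only the compared stages. Nanog lost its call without either depleted system, the filter or the system block.

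At day 6 the genes higher in the depleted change included Dppa5a at 7.66 ± 1.29 (SE, n = 2 systems per class; limma adjusted p = 0.0024), Tdgf1 at 7.01 ± 1.32, Pou5f1 at 6.53 ± 1.76 (adjusted p = 0.029) and Esrrb at 5.93 ± 0.66. Ly6g6c (7.78 ± 1.18), the X-linked homeobox gene Rhox5 (7.32 ± 0.88), Fam25c (7.30 ± 1.16) and Krtdap (5.97 ± 0.83) were higher as well. Lower were Mgp (-9.60 ± 1.05), Igf2 (-9.34 ± 2.30), Igfbp5 (-9.22 ± 1.65), H19 (-8.89 ± 1.43), Acta2 (-8.87 ± 1.35) and Igfbp3 (-8.74 ± 1.92). Of 30 pluripotency genes 17 were higher (23 adjusted over the list alone; camera adjusted p = 6.96e-14, and adjusted p = 0.157 with an estimated correlation). Of 32 fibroblast genes 29 were lower (31 adjusted over the list alone; camera adjusted p = 3.97e-28, and adjusted p = 0.0674 with an estimated correlation). In the epithelial list 5 of 20 were higher, led by the claudin gene Cldn6 (4.58 ± 1.15) and the polarity gene Crb3 (3.83 ± 1.00; 9 up and 1 down adjusted over the list alone; camera adjusted p = 0.000113, and adjusted p = 0.423 with an estimated correlation). In all, 906 genes were higher and 1561 lower (2467), and 2318 and 1885 without Mbd3f/-. Without Mbd3f/-, Gatad2a-/- or WT-2 the count was 4203, 1633 and 796, and 12, 13 and 19 of the 20 named genes kept their call (17 without WT-1). It was 601 without the system block and 882 with only the compared stages. Pou5f1 lost its call in 5 alternatives, among them no filter and leaving out either depleted system.

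By day 8 Dppa5a (7.58 ± 1.29, SE, n = 2 systems per class; limma adjusted p = 0.0020), Rhox5 (7.17 ± 0.88), Zfp42 (6.45 ± 0.73), Dppa3 (6.14 ± 0.66), Tdgf1 (6.05 ± 1.32), and Rpl10l (5.97 ± 1.07) were higher in the depleted change. So were Pou5f1 (5.96 ± 1.76, adjusted p = 0.036), Fam25c (5.92 ± 1.16) and Esrrb (5.91 ± 0.66). Pou5f1 lost this call in 6 alternatives: with a pseudocount of 0.1, without the filter, without the system block, with only the compared stages, and without Mbd3f/- or Gatad2a-/-. Tdgf1 lost its call in 5 alternatives, Igf2 in 4, Igfbp3, Igfbp5 and Lyz2 in 3, Mfap4, Dcn and Rpl10l in 2, Fam25c without WT-2 and Dppa5a without Mbd3f/-. Lower were Mgp (-9.14 ± 1.05), Igf2 (-8.97 ± 2.30), Igfbp5 (-8.76 ± 1.65), Igfbp3 (-8.73 ± 1.92), and Mfap4 (-8.27 ± 1.45). Lyz2 (-8.25 ± 2.2), Thbs2 (-8.15 ± 0.61, adjusted p = 1.9e-05), decorin Dcn (-8.00 ± 1.24), Ptn (-7.84 ± 1.03) and Bgn (-7.55 ± 0.82) were lower too. Of 30 pluripotency genes 21 were higher (24 adjusted over the list alone; camera adjusted p = 6.47e-15, and adjusted p = 0.133 with an estimated correlation). Of the induced factors Sox2 was higher (5.56 ± 1.26), Klf4 had a difference of 1.8 ± 1.32 (adjusted p = 0.382) and Myc of -2.19 ± 2.03 (adjusted p = 0.492). Of 32 fibroblast genes 29 were lower (31 adjusted over the list alone; camera adjusted p = 1.63e-27, and adjusted p = 0.0725 with an estimated correlation). Of 14 smooth muscle and TGF-beta genes 8 were lower (12 adjusted over the list alone; camera adjusted p = 1.9e-09, and adjusted p = 0.131 with an estimated correlation). Of 20 senescence and p53 genes 5 were lower, among them the cell cycle inhibitor genes Cdkn2b (-4.70 ± 1.12), Cdkn1c (-3.56 ± 0.87) and Cdkn2a (-2.61 ± 0.68; 6 adjusted over the list alone; camera adjusted p = 0.00171, and adjusted p = 0.463 with an estimated correlation). Of 18 inflammatory genes 7 were lower, with Cxcl12 at -6.78 ± 1.28 and Mmp3 at -5.89 ± 1.60 (10 adjusted over the list alone; camera adjusted p = 1.72e-07, and adjusted p = 0.279 with an estimated correlation). Of 22 Polycomb and chromatin genes 11 were higher, with Cbx7 at 4.94 ± 0.58 (14 up and 2 down adjusted over the list alone; camera adjusted p = 2.04e-05, and adjusted p = 0.353 with an estimated correlation). Of 14 NuRD genes, Mta3 (2.40 ± 0.46), Gatad2b (2.01 ± 0.48) and 1 more were higher and Chd3 was lower (-2.61 ± 0.62), with no camera call (5 up and 1 down adjusted over the list alone; adjusted p = 0.272).

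At day 8, 1705 genes were higher and 1569 lower in the depleted change (3274), 0.235 being the median difference of all genes, and 0.118 after quantile normalization. The split was 1599 and 1819 after quantile normalization and 338 and 697 without WT-2. Without Mbd3f/-, Gatad2a-/- or WT-2 the count was 4971, 2049 and 1035, and 10, 15 and 16 of the 20 named genes kept their call (17 without WT-1). It was 847 without the system block and 791 with only the compared stages. The WT libraries differed among themselves in the induced factors. Pou5f1 FPKM was 79.1 on day 4 and 171 on day 8 in WT-1. In WT-2 Pou5f1 was listed at 0 from MEF to day 4 and stood at 0.832 on day 8. Sox2 was 6.93 on day 4 and 2.05 on day 8 in WT-1, and 0.237 and 0.265 in WT-2. The epithelial gene Cdh1 was 40.4 on day 4 in WT-1, and was listed at 0 on day 8 in WT-2.

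**Figure D2:**
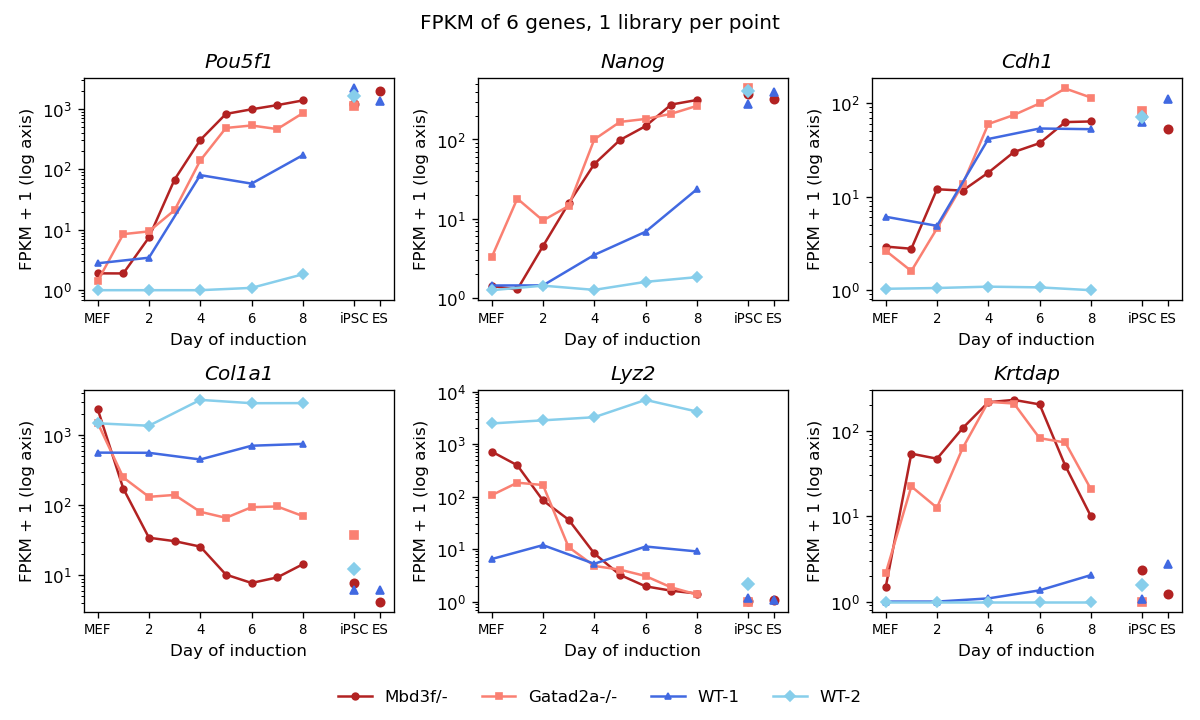
FPKM + 1 (log axis) of Pou5f1, Nanog, Cdh1, Col1a1, Lyz2 and Krtdap by day of induction, with MEF at the left and iPSC and ES at the right of each panel; each point is 1 library and lines join the libraries of a system. Col1a1 went from 2355 in Mbd3f/- MEF to 13.4 on day 8 and from 1466 in WT-2 MEF to 2846 on day 8.

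For established iPSC, the change from MEF differed between the classes in 63 genes, against 493 at day 2. That order turned without Mbd3f/- (2675 against 2265) and without WT-1 (274 against 57). Mme, a membrane peptidase gene, had a larger rise in the depleted systems (4.88 ± 0.81, SE, n = 2 systems per class; limma adjusted p = 0.027). So did Camk1d (3.32 ± 0.46), Fam26e (3.16 ± 0.56), Steap3 (3.14 ± 0.58) and Xlr5c (3.13 ± 0.50). The muscle genes Des (-4.71 ± 0.75, adjusted p = 0.021), Myh11 (-4.16 ± 0.44) and Tnnt2 (-3.73 ± 0.34), the keratin gene Krt18 (-4.37 ± 0.66), Ecscr (-4.08 ± 0.73) and Sprr2k (-3.92 ± 0.55) were lower. Limma called 0 of 30 pluripotency genes, 0 adjusted over the list alone. Camera placed the list lower (adjusted p = 0.0485, and adjusted p = 0.823 with an estimated correlation). The median of -0.35 became 0.09 after quantile normalization, without a call. In the epithelial list Krt18 was the 1 gene of 20 that was lower (2 adjusted over the list alone; camera adjusted p = 1.13e-05, and adjusted p = 0.475 with an estimated correlation). In all, 34 genes were higher and 29 lower (63; 2180 at an unadjusted p under 0.05), 54.0% higher, and 37.8% higher after quantile normalization. Without Mbd3f/-, Gatad2a-/-, WT-1 or WT-2 the count was 2675, 280, 274 and 1. It was 0 with a pseudocount of 0.1 (2166 at an unadjusted p under 0.05) and 0 with only the compared stages (1156). It was 124 without the filter, 5 without the system block, and 139 without the iPSC libraries of Mbd3f/- and WT-1, an alternative chosen after seeing the data.

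Day 8 cells were also set against the iPSC of their own system. In the depleted systems the lectin gene Clec2i was higher on day 8 (4.78 ± 0.39, SE, n = 2 systems; limma adjusted p = 0.00012). So were Tcrg-C1 (4.08 ± 0.26), Dppa3 (3.98 ± 0.47), Cyp2b23 (3.73 ± 0.72), the fatty acid binding protein gene Fabp5 (3.36 ± 0.61), Enpp3 (3.27 ± 0.49) and Krtdap (3.23 ± 0.59). Lower were the ETS factor gene Etv4 (-3.43 ± 0.70, adjusted p = 0.049), the meiotic entry gene Stra8 (-2.93 ± 0.38), Mras (-2.78 ± 0.43), Pla2g1b (-2.65 ± 0.49) and Krt42 (-2.43 ± 0.39). Of 30 pluripotency genes 1 was higher, Dppa3, and 1 adjusted over the list alone (camera adjusted p = 0.604). Of 20 epithelial genes 2 were higher, Krt18 (2.49 ± 0.47) and Rab25 (2.34 ± 0.42; 6 up and 1 down adjusted over the list alone; camera adjusted p = 3.72e-09, and adjusted p = 0.718 with an estimated correlation). Limma called 0 of 32 fibroblast genes (camera adjusted p = 0.917). In all, 65 genes were higher and 50 lower (115; 1407 at an unadjusted p under 0.05). Without Mbd3f/-, WT-1 or WT-2 the count was 2715, 10 and 10, and without Gatad2a-/-, at a count of 86, 3 of 19 named genes kept their call. It was 37 with a pseudocount of 0.1 (34 higher and 3 lower), 210 without the filter and 25 without the system block. It was 0 with only the compared stages (913 at an unadjusted p under 0.05), and 206 without the iPSC libraries of Mbd3f/- and WT-1, an alternative chosen after seeing the data.

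In WT day 8 cells Col1a2 (8.72 ± 1.06, SE, n = 2 systems), Mgp (8.67 ± 0.74), Col3a1 (8.43 ± 0.71) and Cxcl12 (8.17 ± 0.91) were higher than in the iPSC of the same systems. They were followed by Igfbp5 (7.78 ± 1.16), lumican Lum (7.75 ± 1.17), Tmem176b (7.67 ± 0.48), Dcn (7.62 ± 0.88), Cxcl5 (7.57 ± 1.05) and Igf2 (7.56 ± 1.63). Lower were Dppa5a (-7.92 ± 0.91), Upp1 (-7.01 ± 0.88), Pou5f1 (-6.74 ± 1.25), Sept1 (-6.47 ± 0.74) and Sox2 (-6.41 ± 0.89). Next came Tdgf1 (-6.32 ± 0.94), Trap1a (-6.19 ± 0.47), Esrrb (-6.03 ± 0.47), Pla2g1b (-5.95 ± 0.49) and Utf1 (-5.87 ± 0.70). Of 30 pluripotency genes 29 were lower (30 adjusted over the list alone; camera adjusted p = 3.97e-18, and adjusted p = 0.142 with an estimated correlation). Of 32 fibroblast genes 30 were higher (31 adjusted over the list alone; camera adjusted p = 6.69e-24, and adjusted p = 0.114 with an estimated correlation). Of 38 cell cycle genes 37 were lower, and 37 adjusted over the list alone (camera adjusted p = 1e-14, and adjusted p = 0.295 with an estimated correlation). Of 24 glycolysis genes 15 were lower and 1 higher, with Slc2a3 at -5.52 ± 0.85 (16 and 1 adjusted over the list alone; camera adjusted p = 0.00011, and adjusted p = 0.404 with an estimated correlation). Of 20 senescence genes 9 were higher, with Cdkn1c at 4.54 ± 0.62 and Cdkn2b at 4.46 ± 0.79 (10 adjusted over the list alone; camera adjusted p = 0.000427, and adjusted p = 0.392 with an estimated correlation). By limma 3194 genes were higher and 3977 lower (7171). Without WT-2, 1689 genes passed (1125 higher and 564 lower) and Igf2 lost its call; without the system block 2833 passed, and with only the compared stages 4557.

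The daily libraries of the depleted systems divide the course into an early, a middle and a late window. On day 1 the pluripotency-associated gene L1td1 (5.58 ± 0.84, SE, n = 2 systems; limma adjusted p = 0.00090), the aldehyde dehydrogenase gene Aldh3a1 (5.50 ± 0.40), Shisa3 (4.75 ± 0.51), Krtdap (4.29 ± 0.66), and Gpr50 (4.15 ± 0.47) had risen. Rises followed for Pcolce2 (4.02 ± 0.52), Fetub (4.00 ± 0.43), Rapgef4 (3.97 ± 0.39), Aqp3 (3.95 ± 0.51) and Plek2 (3.93 ± 0.46). Among the falls were Aspn at -4.90 ± 0.44, Ibsp at -4.76 ± 0.87, Ogn at -4.65 ± 0.52, Col12a1 at -4.16 ± 0.47, Itga11 at -4.13 ± 0.39, Mfap2 at -4.08 ± 0.52 and Cxcl12 at -4.08 ± 0.53. Ribosome biogenesis genes rose in 44 of 45 cases, with the nucleolar genes Nolc1 (3.17 ± 0.41) and Nhp2 (3.15 ± 0.48), and in 44 adjusted over the list alone (camera adjusted p = 8.97e-24, and adjusted p = 0.241 with an estimated correlation). Cell cycle genes rose in 34 of 38 cases, with Mcm5 (2.72 ± 0.37) and the ribonucleotide reductase gene Rrm2 (2.71 ± 0.33), and in 35 adjusted over the list alone (camera adjusted p = 2.11e-22, and adjusted p = 0.0562 with an estimated correlation). Fibroblast genes fell in 22 of 32 cases (23 adjusted over the list alone; camera adjusted p = 1.03e-15, and adjusted p = 0.0919 with an estimated correlation). Oxidative phosphorylation genes rose in 21 of 32 (25 adjusted over the list alone; camera adjusted p = 1.07e-08, and adjusted p = 0.241 with an estimated correlation). Of 30 pluripotency genes 5 rose and 1 fell, and 5 and 1 adjusted over the list alone (camera adjusted p = 0.483). Of 14 NuRD genes 6 rose, Mbd3 among them (0.86 ± 0.28; 7 adjusted over the list alone; camera adjusted p = 0.0468, and adjusted p = 0.188 with an estimated correlation), a list call that ended under either scaling. In all 2858 genes rose and 1818 fell (4676), 61.1% up, and 47.5% up with upper quartile scaling. Leaving out the system block, 1325 passed (648 up and 677 down) and Mfap2 lost its call, as Ibsp did with only the compared stages.

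The window from day 1 to day 4 holds the change of medium and the start of the feeder layer. Pou5f1 rose by 5.69 ± 0.69 (SE, n = 2 systems; limma adjusted p = 0.00062), Lgals7 by 5.48 ± 0.66, the calcium pump gene Atp2a3 by 4.96 ± 0.32, Ly6g6c by 4.58 ± 0.90 and Tdgf1 by 4.55 ± 0.71. The near-identical small nuclear RNA genes Rnu1b2 (5.44 ± 1.32), Rnu1b1 (5.44 ± 1.32) and Rnu1b6 (5.02 ± 1.33) also rose; reads cannot be divided among them with certainty. Falls were largest for Fxyd5 (-5.64 ± 0.41), Bgn (-5.63 ± 0.49), and Serpinf1 (-5.42 ± 0.45). Next came Lyz2 (-5.42 ± 0.74), Lgals3bp (-5.32 ± 0.44), the platelet gene Pf4 (-5.22 ± 0.69), Fcer1g (-4.91 ± 0.59), the complement gene C1qa (-4.90 ± 0.51) and Tyrobp (-4.88 ± 0.56). Macrophage and blood markers fell in 6 of 8 cases (7 adjusted over the list alone; camera adjusted p = 3.44e-08, and adjusted p = 0.164 with an estimated correlation). Interferon genes fell in 11 of 19 cases, with Isg15 at -4.82 ± 0.98 and Irf7 at -3.44 ± 0.78 (16 adjusted over the list alone; camera adjusted p = 7.26e-10, and adjusted p = 0.164 with an estimated correlation). Epithelial genes rose in 10 of 19 cases, with Cldn4 at 4.20 ± 0.52 and Cdh1 at 3.96 ± 0.65 (12 adjusted over the list alone; camera adjusted p = 2.3e-11, and adjusted p = 0.154 with an estimated correlation). Pluripotency genes rose in 10 of 30 cases, with Nanog at 3.87 ± 0.77 (15 adjusted over the list alone; camera adjusted p = 2.3e-11, and adjusted p = 0.164 with an estimated correlation). Fibroblast genes fell in 21 of 32 cases (28 adjusted over the list alone; camera adjusted p = 1.42e-21, and adjusted p = 0.0651 with an estimated correlation). Glycolysis genes rose in 3 of 24 cases, Aldoc (4.27 ± 0.87), Slc2a3 (3.17 ± 0.45) and Slc2a1 (2.46 ± 0.60; 4 adjusted over the list alone; camera adjusted p = 9.51e-06, and adjusted p = 0.308 with an estimated correlation). Among signs of RNA quality 1 of 9 rose, the non-coding RNA Rpph1 (3.83 ± 1.05; 2 adjusted over the list alone; camera adjusted p = 0.0109, and adjusted p = 0.164 with an estimated correlation). In all 398 genes rose and 1323 fell (1721). The fit without the system block called 541, where Ly6g6c and the 3 Rnu1b genes lost their call. With only the libraries of the compared stages 743 passed, where Pou5f1 and the 3 Rnu1b genes lost it; Rnu1b6 also lost it without the filter.

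Between day 4 and day 8, Dppa5a rose by 8.86 ± 0.57 (SE, n = 2 systems; limma adjusted p = 1.1e-05). It was followed by osteopontin Spp1 (6.70 ± 0.81), Trap1a (6.08 ± 0.38), Ifitm1 (6.07 ± 0.64), Dnmt3l (5.84 ± 0.94), Rpl10l (5.64 ± 1.01), the oocyte gene Ooep (5.38 ± 0.54), Hsf2bp (5.12 ± 0.38), Dppa4 (5.11 ± 0.26) and Mep1b (5.10 ± 0.66). Falls were those of embryonic globin Hbb-y (-4.44 ± 1.05), the surface genes Cd44 (-4.25 ± 0.44), Cd24a (-3.84 ± 0.31) and Nt5e (-3.72 ± 0.60), Lgals7 (-3.99 ± 0.66), Eya2 (-3.94 ± 0.45) and Krtdap (-3.92 ± 0.66). Pluripotency genes rose in 20 of 30 cases (26 adjusted over the list alone; camera adjusted p = 6.28e-20, and adjusted p = 0.199 with an estimated correlation). Germline genes rose in 9 of 19, with Dazl at 3.40 ± 0.81 and Hormad1 at 3.24 ± 0.32 (14 up and 1 down adjusted over the list alone; camera adjusted p = 6.15e-07, and adjusted p = 0.49 with an estimated correlation). Ribosome biogenesis genes fell in 4 of 45 cases, with the spermidine synthase gene Srm at -1.59 ± 0.41 (4 adjusted over the list alone; camera adjusted p = 5.21e-07, and adjusted p = 0.591 with an estimated correlation). The list calls for ribosomal protein genes (5 of 39 lower, 6 adjusted over the list alone; camera adjusted p = 5.21e-07, and adjusted p = 0.591 with an estimated correlation) and oxidative phosphorylation genes (6 of 32 lower, 8 adjusted over the list alone; camera adjusted p = 2.74e-06, and adjusted p = 0.49 with an estimated correlation) ended after quantile normalization. In all 1864 genes rose and 904 fell (2768), 67.3% up, and 50.6% up after quantile normalization. Without the system block 773 passed, and with only the compared stages 754, with Hbb-y losing its call in both and Cd44 in the former.

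ES of Mbd3f/- and WT-1 were set against iPSC class means, which include Gatad2a-/- and WT-2. Limma called 0 genes (515 at an unadjusted p under 0.05). The mesoderm gene Cdx1 had a difference of -2.72 ± 0.52 (SE, 1 ES library per class), and Zscan4f, a 2-cell-stage gene, of 1.48 ± 0.73. Neither was called. Camera placed 14 2-cell-like genes higher (adjusted p = 9.42e-14, and adjusted p = 0.652 with an estimated correlation) and ribosomal protein genes lower in ES (adjusted p = 1.41e-13, and adjusted p = 0.793 with an estimated correlation), with 0 members called. Without Mbd3f/-, Gatad2a-/-, WT-1 or WT-2 the count was 682, 33, 43 and 2. It was 5 with a pseudocount of 0.1, 77 without the filter, 4 after quantile normalization and 4 among protein-coding genes only. From iPSC to ES, Mbd3f/- and WT-1 ran opposite ways in single genes. The maternally expressed imprinted RNA Meg3 had an FPKM of 4.21 in ES and 70.0 in iPSC of Mbd3f/-, and 58.8 in ES and 4.29 in iPSC of WT-1. Dnmt3l was 113 and 12.6 in Mbd3f/-, and 28.5 and 189 in WT-1; these genes were chosen after their values were seen.

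The Myc table asks how Myc contributes, in Mbd3f/- cells induced with OSK (Oct4, Sox2 and Klf4) with or without Myc and in a second Mbd3f/- line that carries OSK without a Myc transgene. Per the labels, that line received small interfering RNA against the Myc family on day -3 and on day 0, a control RNA (si-Scramble) or a Myc inhibitor. Myc (ENSMUSG00000022346, chromosome 15 at 61985391 to 61990374, plus strand, 3 exons) had an FPKM of 3.16 in the library labelled OSK plus Myc, 0.51 in the library labelled Myc alone and 24.8 in the library labelled OSK alone, lower where Myc was added. It was 11 in the library labelled siMyc Day7 and 16.2 in its control, and 29.2 in the library labelled siMyc Day3, 29.4 with the inhibitor and 30.5 and 26.5 in the control MEF. Mycl was 11.7, 0.608 and 4.63 in the libraries labelled OSK plus Myc, Myc alone and OSK alone, and Mycn 0.354, 0.177 and 4.17. Mycl was 3.31 in siMyc Day7 and 1.03 in its control, and 3.93 in siMyc Day3 against 1.65 and 1.29 in the control MEF, higher where the label names small interfering RNA against the family. Mycn was 0.927 against 1.47, and 1.87 against 5.11 and 4.43. Every direction given for this table rests on these labels. There is 1 library per condition, so no difference has a replicate check. The 2 control MEF libraries differed by at least 2-fold in 374 of 16436 genes, with an SD of the log2 difference of 0.589 across genes.

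In the library labelled OSK plus Myc against that labelled OSK alone, 1828 genes were at least 2-fold higher and 2573 lower (4401), or 2211 and 2110 after quantile normalization. Paralogous replication histone genes, whose RNA mostly lacks a poly(A) tail, were among the highest, with Hist1h2ap at 133 against 0.12 FPKM and Hist1h2ao at 74.7 against 0.137. Interferon-induced GTPase genes were among the lowest, with Tgtp1 at 0.362 against 100 and Igtp at 0.298 against 94.3, beside the granule proteoglycan gene Srgn at 0.413 against 131. The ribosome biogenesis and Myc-responsive list had a median log2 ratio of 1.21, above every random list (percentile 100), and the interferon list of -2.77 (percentile 0). The cell cycle list was at -0.75 (percentile 0), the senescence and p53 list at 1.12 (percentile 100) and signs of RNA quality at 2.38 (percentile 100). Against the library labelled Myc alone, OSK plus Myc was higher in 1449 genes and lower in 654 (2103; 3377 with a pseudocount of 0.1). Higher were Sox2 (312 against 0.821), Fetub (174 against 0.798), the neurofilament gene Nefl (91.2 against 0.0776), L1td1 (76.1 against 0.0526) and Krtdap (62.1 against 0.331), and Aldh3a1 stood at 304 while listed at 0 with Myc alone. The epithelial list was at 1.79 (percentile 100) and the keratinocyte list at 2.03 (percentile 100). The library labelled Myc alone against OSK alone was higher in 2066 genes and lower in 3228 (5294), or 2706 and 2482 after quantile normalization, with the ribosome biogenesis list at 1.45 (percentile 100).

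In the library labelled siMyc Day7 against its control, 513 genes were at least 2-fold higher and 686 lower (1199; 2029 with a pseudocount of 0.1). Interferon-induced GTPase genes were higher, with the near-identical pair Tgtp1 (182 against 2.44) and Tgtp2 (249 against 5.14), Iigp1 (232 against 8.89) and Igtp (147 against 10.1), as were Map6 (55.6 against 0.375) and the melanocyte factor gene Mitf (54.8 against 1.02). Serpinb2 (1.01 against 39.5), Lgals7 (5.32 against 76.8), Upk3b (5.74 against 78.6), Ptn (7.53 against 93.6) and Lum (10.8 against 128) were lower. The interferon list had a median of 0.77 (percentile 100), smooth muscle and TGF-beta genes of 0.60 (percentile 100) and ribosome biogenesis genes of 0.15 (percentile 93.05). Medians under 0 were those of cell cycle genes at -0.54 (percentile 0), fibroblast genes at -0.58 (percentile 0), epithelial genes at -0.57 (percentile 0) and pluripotency genes at -0.25 (percentile 2.8). In the library labelled siMyc Day3 against the control MEF, a contrast that also holds 3 days of induction, 751 genes were higher and 1373 lower (2124; 3567 with a pseudocount of 0.1). After quantile normalization the split was 997 and 980, and the median of all genes moved from -0.145 to -0.00611. Aldh3a1 (164 against 0.0182), Fetub (75.2 against 0.275), the keratin genes Krt13 (66.6 against 0.254) and Krt16 (39.7 against 0.263) and Aqp3 (55.7 against 0.64) were higher. The hypoxia-responsive genes Car9 (0.356 against 44.9) and Ndufa4l2 (12.2 against 378) were lower. With the inhibitor, 1654 genes were higher and 1695 lower (3349), with Upk3b (0.194 against 94), Saa3 (0.182 against 50.7) and S100a4 (16.1 against 703) lower and Prelp (163 against 4.78) and Gdf15 (108 against 5.24) higher. The libraries labelled siMyc Day3 and Myc inhibitor Day3 differed directly in 4663 genes (1883 higher, 2780 lower with siMyc, or 2327 and 2201 after quantile normalization). In the inhibitor library the Y-linked genes Ddx3y and Eif2s3y stood at 0.0535 and 0.422, against 8.71 to 13.3 and 25.9 to 40.9 in the other libraries of the table. The comparisons with it may therefore hold a difference of animal or line as well. The cell cycle list was at -0.93 (percentile 0) with the inhibitor, -0.11 (percentile 62.29) with siMyc and 0.79 (percentile 100) between them, and the keratinocyte list at -0.02, 1.46 (percentile 100) and 2.11 (percentile 100). Ribosome biogenesis was at -0.14 (percentile 47.68) with the inhibitor and 0.30 (percentile 100) with siMyc.

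**Figure D3:**
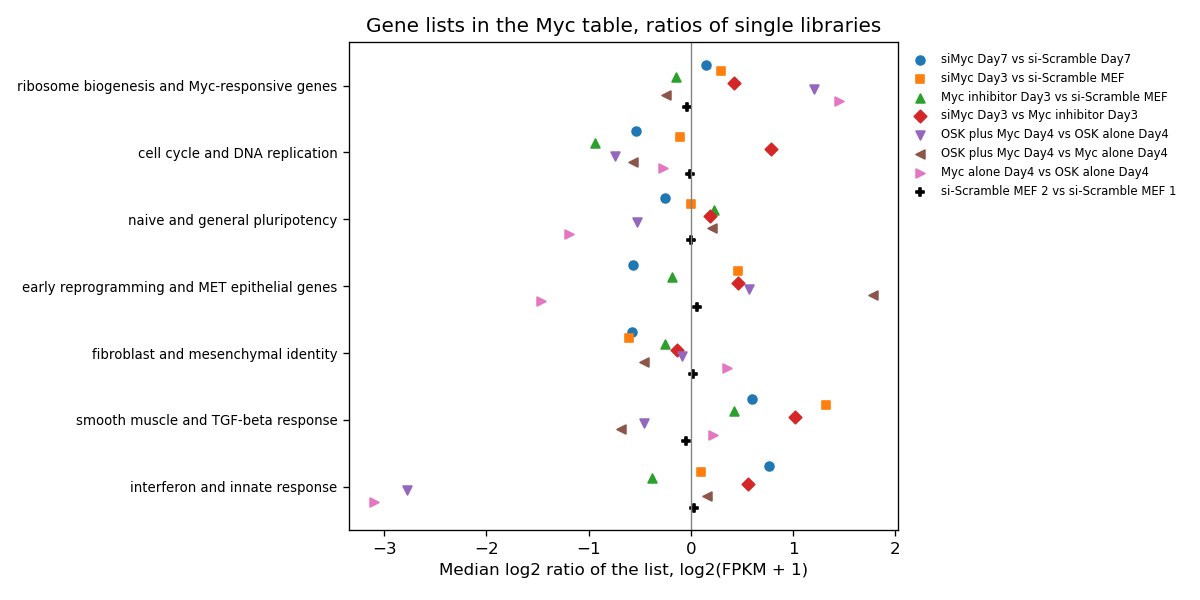
Median log2 ratio (horizontal axis, log2(FPKM + 1)) of 7 gene lists in 8 comparisons of libraries of the Myc table; each point is a list median, and the 2 control MEF replicates give the replicate level. Ribosome biogenesis stood at 1.21 for the library labelled OSK plus Myc and at 1.45 for that labelled Myc alone, each against OSK alone, and at -0.04 between the replicates.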

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

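The test of whether 1 system alone made the day 8 difference was chosen only after the result was seen; the counts of other splits were planned. The depleted and WT systems differed in their change from MEF, by the interaction test in limma, in 493 genes at day 2, 1310 at day 4, 2467 at day 6, 3274 at day 8 and 63 in iPSC. Each count moved by over 1.5 times when 1 system was left out. It was lowest without WT-2: 49 at day 2, 241 at day 4, 796 at day 6, 1035 at day 8 and 1 in iPSC. It was highest without Mbd3f/-: 2265, 3336, 4203, 4971 and 2675. Without Gatad2a-/- it was 851 at day 2, 1633 at day 6, 2049 at day 8 and 280 in iPSC, and without WT-1 57 at day 2, 710 at day 4 and 274 in iPSC.

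The day 8 difference of 3274 genes, in which Dppa5a and Zfp42 were higher and Mgp and Thbs2 lower in the depleted change, may reflect the loss of Mbd3 or Gatad2a, or other differences between these lines. Leaving out 1 system cannot tell whether 1 system made it alone, since a class left with 1 system has no spread of its own. The 4 systems allow 3 splits into pairs, too few for a share under 0.05; the real split was the 1 with the highest count, and the highest other called 0. Also open is how far the transgenes were induced in WT-2, where Pou5f1 stood at 0.832 FPKM and Sox2 at 0.265 on day 8. So is genetic background, which the design ties to the class in all systems but Gatad2a-/- and WT-2. For iPSC against MEF, the real 1 of 34 splits of the 8 libraries called most genes (10587 in that model). The highest other, 3747, kept MEF and iPSC apart in Mbd3f/- and WT-2. Many splits put both libraries of a system on 1 side, so chance is not excluded.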

How the results depend on the processing

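Protein-coding genes only and leaving out iPSC of Mbd3f/- and WT-1 were chosen after seeing the data. Named genes kept their sign, largely fixed by the naming rule and, without the block or eBayes options, by an equal estimate. Called lists, not run without a system, kept their camera direction. The median of 1, pluripotency genes in the iPSC difference, turned without a call. Of 159 counts of called genes under alternatives, 93 were within 1.5 times of the reported count and 66 were not; of 2945 checks of named genes 2392 kept the call and 553 lost it, and of 615 checks of called lists 380 kept it and 235 lost it. Progress of a library stayed within the spread between systems in 74 of 78 checks, and the Myc counts within 1.5 times in 29 of 32. Upper quartile scaling, and eBayes without trend and robust, moved no count by over 1.5 times. The causes were not tested, but fewer libraries leave fewer residual degrees of freedom.

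With a pseudocount of 0.1 the depleted against WT difference fell to 255 genes at day 2 and to 0 in iPSC (2166 at an unadjusted p under 0.05 in limma), depleted day 8 against iPSC gave 37 and ES against iPSC 5. In the Myc table it gave 2029 genes for siMyc Day7, 3567 for siMyc Day3 and 3377 for OSK plus Myc against Myc alone. Without the filter, WT day 8 against MEF gave 112, the class difference 306 at day 2 and 124 in iPSC, depleted day 8 against iPSC 210 and ES against iPSC 77. After quantile normalization ES against iPSC gave 4. Without the system block the counts were 6411 for iPSC against MEF, 2910 for depleted and 1 for WT day 8 against MEF, 28, 205, 601 and 847 for the class difference at days 2, 4, 6 and 8 and 5 in iPSC, 25 for depleted and 2833 for WT day 8 against iPSC, and 1325, 541 and 773 for the windows to day 1, day 4 and day 8. With only the libraries of the compared stages they were 4588 for depleted and 0 for WT day 8 against MEF (1930 unadjusted), 0 (3689 unadjusted), 283, 882 and 791 for the class difference at days 2, 4, 6 and 8 and 0 in iPSC (1156 unadjusted), 0 for depleted (913 unadjusted) and 4557 for WT day 8 against iPSC, and 743 and 754 for the later windows. Among protein-coding genes only, the class difference at day 2 gave 799 and ES against iPSC 4. Without the iPSC libraries of Mbd3f/- and WT-1, the class difference in iPSC gave 139 and depleted day 8 against iPSC 206. Of the 205 camera calls, 0 held with an estimated correlation, 184 after quantile normalization and 196 with upper quartile scaling.

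The larger side of a count, higher or lower, turned in 24 of 148 checks of the course and in 7 of 32 of the Myc table. For the class difference it turned without Mbd3f/- to 1464 higher and 801 lower at day 2, 1963 and 1373 at day 4 and 2318 and 1885 at day 6. At day 8 the reported 1705 and 1569 became 1693 and 1695 with a pseudocount of 0.1, 1599 and 1819 after quantile normalization, 344 and 503 without the system block, 313 and 478 with only the compared stages, 338 and 697 without WT-2 and 1617 and 1665 among protein-coding genes only. In iPSC it turned in 5 checks, with 17 and 28 after quantile normalization. WT day 8 against MEF gave 217 and 105 without WT-2, and WT day 8 against iPSC 1125 and 564. Depleted day 8 against MEF gave 1327 and 1583 without the system block, day 1 against MEF 648 and 677 and WT day 8 against iPSC 1578 and 1255. Day 1 against MEF gave 2130 and 2355 with upper quartile scaling, and WT day 8 against iPSC 2375 and 2182 with only the compared stages. The cause of these turns was not tested.

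Leaving out 1 system at a time gave 7681 to 11060 genes for iPSC against MEF, 4023 to 6131 for depleted day 8 against MEF and 1 to 322 for WT day 8 against MEF. It gave 49 to 2265, 241 to 3336, 796 to 4203 and 1035 to 4971 for the class difference at days 2, 4, 6 and 8, 1 to 2675 in iPSC, 10 to 2715 for depleted and 1689 to 7155 for WT day 8 against iPSC, and 2 to 682 for ES against iPSC. A class left with 1 system is assumed to vary like the other. Leaving out a system was not run for the dense course, because 1 system leaves no residual degrees of freedom, and neither was the fit of ES with only the compared stages. Depth is unknown, so counting error at low FPKM cannot be set apart from the spread between libraries.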

Other observations

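The tests of exchanged libraries, of MEK inhibition and of the Myc labels were chosen only after the results were seen; the test of GC content and length was planned. The genes followed here were picked after their values were seen, and levels in different tables were normalized separately. The epidermal genes Krtdap and Lgals7 rose and fell again within the depleted courses. Of the fixed keratinocyte list, camera placed the 8 measured markers higher between day 1 and day 4 (adjusted p = 0.00195, and adjusted p = 0.256 with an estimated correlation), with no call between day 4 and day 8 (adjusted p = 0.103). Krtdap FPKM was 0.466 in Mbd3f/- MEF, 53 on day 1, 215 on day 4, 229 on day 5 and 8.97 on day 8, and in Gatad2a-/- 1.14 in MEF, 217 on day 4, 208 on day 5 and 19.7 on day 8. It was listed at 0 in WT-2 from MEF to day 8, and was 0.0892 on day 4 and 1.04 on day 8 in WT-1. Lgals7 was 206 on day 4 and 5.25 on day 8 in Mbd3f/-, and 71.6 and 8.51 in Gatad2a-/-. By limma both fell between day 4 and day 8. Macrophage lysozyme Lyz2 went from 719 in MEF to 0.425 on day 8 in Mbd3f/- and from 105 to 0.365 in Gatad2a-/-, while in WT-2 it was 2466 in MEF, 6935 on day 6 and 4157 on day 8, and in WT-1 5.45 in MEF and 8.02 on day 8. Myc itself took different courses: in Mbd3f/- 13.0 in MEF and 0.0919 on day 4, in Gatad2a-/- 19.4 and 44.4, in WT-1 17.2 and 129, and in WT-2 19.6 and 6.15.

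Hprt, a purine salvage gene on chromosome X at 52988137 to 53021659, ranged from 0.324 to 8.91 FPKM in Mbd3f/- libraries, from 75.6 to 158.5 in WT-1, from 72.8 to 171.7 in Gatad2a-/- and from 43.6 to 112.5 in WT-2. The Y-linked gene Ddx3y was 4.22 in WT-2 MEF and 0.0336 in WT-2 iPSC, so the WT-2 comparisons with iPSC may hold a difference of animal or line as well. The Gatad2a-/- library sums of FPKM ran from 1494230 to 10044700, against 573675 to 707073 in Mbd3f/-.

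The change from iPSC to ES ran opposite ways in Mbd3f/- and WT-1, with a correlation of -0.696 over 13405 genes, which are not independent replicates; Junb was 0.491 in ES and 11.4 in iPSC of Mbd3f/-, and 9.08 and 0.666 in WT-1. A trend in GC content and length, known for 98.77% of these genes, took 20.8% and 11.5% of the variance in the 2 systems and left a correlation of -0.665, which argues against it as the whole cause. An exchange of libraries between the systems is unlikely, since Hprt was 0.969 FPKM in the higher of the ES and iPSC libraries labelled Mbd3f/-, and 75.6 in the lowest WT-1 library. An earlier test went the other way: of 416 genes that part the systems up to day 8, 26.2% kept their side in both ES and iPSC, while 44.7% changed side in ES alone and 13.7% in iPSC alone. An exchange of the ES and iPSC labels within 1 system was not tested and would give this pattern. The ES library of Mbd3f/- correlated at 0.9591 with WT-1 iPSC and its iPSC library at 0.9483 with WT-1 ES, against 0.9245 and 0.9264 within the systems. Culture with and without MEK inhibition cannot be told apart from other causes: of 10 MEK-responsive genes 5, including Spry4 and Dusp6, ran opposite ways in 1 order and 2 in the other. Such an exchange, which would change the iPSC end point of that system, stays open beside culture, passage and differences between the lines.

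Myc was lower in the libraries labelled with added Myc, at 3.16 and 0.51 FPKM against 24.8 in that labelled OSK alone. Transgenic Myc may not be counted in the mouse Myc gene while the endogenous gene is repressed. In OSK plus Myc against OSK alone, the ribosome biogenesis and Myc-responsive list had a median of 1.21 (percentile 100 of random lists). It was 0.15 in siMyc Day7, 0.30 in siMyc Day3 and under 0 with the inhibitor, so it cannot decide between uncounted Myc and exchanged labels. With OSK plus Myc, cell cycle genes lay at percentile 0, which does not go with added Myc. Senescence and p53 genes and signs of RNA quality lay at percentile 100, so differences other than Myc stay open. The transgene sequence was not analysed, and 1 library per condition gives no replicate check.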
